A study of Mus musculus with 8 samples.

How the data were processed

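The series holds RNA-seq of 8 whole TH-MYCN mouse neuroblastomas, 4 from animals given panobinostat and 4 from animals given vehicle, with 1 library per animal. Total RNA was made into libraries with a TruSeq kit, per the labels. The submitters' processing notes name CASAVA 1.8.2, TopHat2, HTSeq, limma and the mouse build mm10, without saying which step each served. The annotation, the filter, the normalization and whether counting used strand are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart.

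The deposited table gives 1 log2 value per gene and library for 17488 genes. Its values have the form that voom in limma writes, log2 CPM (counts scaled to an effective library size) with 0.5 added to each count, as the values themselves show: whole reads came back for 100% of values within a tolerance of 0.001 read (largest distance 7.59e-04). The lowest total over the 8 libraries was 13 reads for any listed gene. The effective library size that the authors used was 0.939 ± 0.041 times the read total in vehicle libraries and 1.02 ± 0.013 times in panobinostat libraries (mean ± SD, n = 4, two-sided exact permutation p = 0.0286, the smallest that 70 assignments allow). This is a log2 shift of 0.119 between groups relative to read totals. Read totals, here sums over the listed genes, were 22055658 to 23830026 with vehicle and 18664066 to 22235545 with panobinostat (p = 0.0571 for the difference of means, same exact test). Genes at 0 reads numbered 132 to 213 in vehicle and 6 to 39 in panobinostat libraries.

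Groups were taken from the labels. The numbers in the sample codes are all lower for vehicle than for panobinostat. The sample details used here hold no cohort, litter or processing date. A difference of that kind between the groups could not be told apart from treatment. Replicate numbers only name the samples and pair nothing. Gene identifiers were matched to symbols in a reference table, which gave 17228 symbols and left 260 identifiers without one. Coordinates come from GENCODE M21, whose assembly is that of mm10, matched by identifier.

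Genes with at least 1 CPM in at least 4 of the 8 libraries were tested, 16157 in all, which left out 1331. The log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on the 2 groups with no covariate. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. Adjusted p-values of genes are from this fit. No pseudocount was added beyond the 0.5 reads in the deposited values, so changes of genes near 0 reads are understated, and reads are given for these in place of folds. Gene lists, 32 of them, were fixed before the data were examined: 19 of pathways, 11 of other cell types or neighbouring organs and 2 of tissue handling or RNA quality. Lists with at least 3 tested members were tested with camera in limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 31 lists. Counts of members are over all genes tested, and for 22 of the 32 lists the counts adjusted over the list alone were identical. Where they differ both are given.

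The genes named were fixed by a rule before the data were examined: the 8 largest increases and 8 largest decreases among changed genes whose groups did not overlap and whose mean was at least the median of tested genes, the 3 members of each pathway list and the 2 members of each other list with the smallest adjusted p, and Mycn, Cdkn1a, H1f0 and each HDAC gene. This made 104 genes, of which some are not reported here. Any gene named beyond the rule was chosen after its value was seen. The fit was tested on simulated counts for the same 16157 genes and library sizes, with 200 genes changed: 58% of 2-fold and 84% of 4-fold changes were recovered, and 5 calls (3.4%) were false. Far fewer genes changed there than were called in the data, and genes varied independently with known library sizes. These rates may therefore not hold for the data.

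Alternatives were no filter, a filter of 5 CPM, no variance trend, robust variance, library weights, quantile normalization, centring on the median or a trimmed mean, an added pseudocount of 1 CPM, an adjusted p of 0.01, a test against a 1.5-fold change, leaving out each library in turn, and camera with an estimated correlation or fry for lists. The difference of mean within-group distances (1 minus Pearson's r, or Euclidean distance over the 1000 most variable genes as an alternative) was tested by exact permutation. Scaling to read totals, voom weights on the recovered reads and leaving out panobinostat libraries 3 and 4 together were added after the data were seen.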

Results

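RNA sequencing was read from whole neuroblastomas of 8 mice homozygous for TH-MYCN, a transgene that drives human MYCN from the tyrosine hydroxylase promoter and gives rise to tumours of the sympathetic ganglia and adrenal medulla. Treatment began at about 6 weeks of age, when tumours measured 200 to 300 mm3. Animals in the treated group (n = 4) received 2 doses of 5 mg/kg panobinostat, a hydroxamate that inhibits the zinc-dependent histone deacetylases (HDACs), and 4 animals received vehicle. Tumours were taken 4 h after the last dose, and each library held tumour and stroma together. Summed over the 17488 listed genes, the libraries held 22055658 to 23830026 reads with vehicle and 18664066 to 22235545 with panobinostat. At this depth 1 CPM, a count scaled to library size, corresponded to 19.3 to 22.6 reads. The comparison asks which transcripts differed in TH-MYCN tumours after about a day of HDAC inhibition.

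Panobinostat-treated tumours held fewer transcripts of most genes of cell division, DNA replication, ribosome biogenesis and sympathoadrenal identity than vehicle-treated tumours. All 30 measured mitosis genes fell, with a median log2 change of -1.34, and 29 of 32 DNA replication genes fell, with a median of -1.27. Of 24 noradrenergic identity genes 14 fell and 2 rose. The neural crest transcription factor gene Tfap2b fell by 2.76 on the log2 scale (SE 0.16, n = 4 per group). In the same tumours 16 of 20 genes often reported to respond to HDAC inhibitors rose, with a median of 1.35, as did 19 of 24 interferon-stimulated genes (median 1.67) and 11 of 13 genes of MHC class I presentation (median 1.94). Markers of macrophages (median 2.22) and of fibroblasts and mural cells (median 2.16) were higher too. None of these lists passed camera with an estimated correlation (adjusted p from 0.397 to 0.508). The panobinostat libraries held reads of adrenal cortex, liver, pancreas or kidney genes at levels not seen with vehicle.

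Of 16157 genes tested with limma, 10289 (63.7%) changed at a Benjamini-Hochberg adjusted p under 0.05, 5048 higher and 5241 lower with panobinostat, and 4988 passed a test against a 1.5-fold change. The split was 4515 higher and 6064 lower with libraries centred on their medians, against 5671 and 4612 with libraries scaled to read totals. The change was at least 2-fold for 3346 of the higher and 2189 of the lower genes, and at least 4-fold for 1481 and 273. In 9646 genes (59.7% of those tested) the 4 values of one group all lay on the same side of the 4 values of the other, which chance gives for 2.86% of genes. Without panobinostat libraries 3 and 4, which held the most reads of liver, pancreas and kidney genes in sum, 7828 genes changed. This comparison was chosen after the data were seen, and 7790 of those genes were also among the 10289, in the same direction. Both fits share all the remaining libraries, so this overlap cannot count as support. Organ reads were not all removed, since 7 of 8 tested adrenal cortex genes were still higher.

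The genes with the largest increases among well expressed genes whose groups did not overlap were Car3, Cyp2e1, Spp1, Star, Itih4, Hist1h1c, Neat1 and Adipoq. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 4.87 ± 1.13 to 9.42 ± 0.73 log2 CPM (mean ± SD, n = 4), a log2 change of 4.55 (SE 0.55). Hist1h1c, a linker histone gene on chromosome 13 (23738808 to 23740367, mm10), rose by 4.40 (SE 0.33), and the long noncoding RNA Neat1 on chromosome 19 (5824708 to 5845478), which scaffolds paraspeckles, rose by 4.13 (SE 0.36). Car3 (5.13, SE 0.67), Cyp2e1 (5.00, SE 0.94) and Adipoq (4.08, SE 0.71) are abundant in fat or liver. They varied widely among vehicle tumours, with Adipoq at 51 to 693 reads there and at 1926 to 3195 reads with panobinostat. Itih4, a liver gene, held 1417 to 9305 reads with panobinostat and 17 to 1235 with vehicle, and its call was lost without panobinostat libraries 3 and 4 (log2 change 3.43, adjusted p = 0.0883, limma). Star, which moves cholesterol into mitochondria for steroid synthesis, had 161 to 223 reads in vehicle tumours and 412 to 20269 with panobinostat.

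Among the largest decreases were those of Agtr2, Lrrc4b, Rtl1, Prrt4, Prr36, St8sia1 and Faxc. Agtr2, the angiotensin II type 2 receptor gene on chromosome X (21484544 to 21489164), went from 10.31 ± 0.41 to 6.41 ± 0.89 log2 CPM (mean ± SD, n = 4), a log2 change of -3.89 (SE 0.40). St8sia1, which encodes GD3 synthase, the enzyme that opens the b-series gangliosides from which GD2 is made, fell by 2.89 (SE 0.14), and the imprinted gene Rtl1 fell by 3.17 (SE 0.13).

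**Figure D1:**
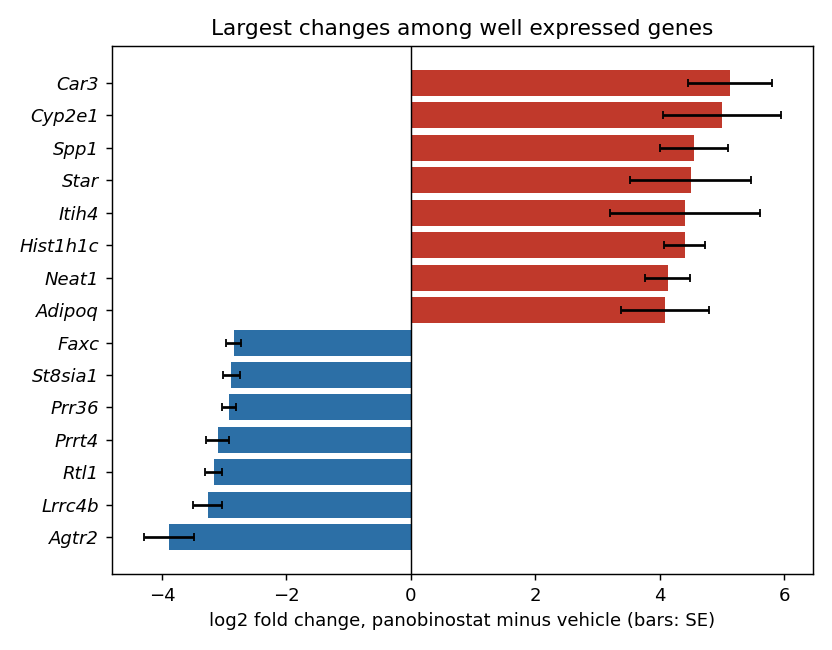
Log2 fold change, panobinostat minus vehicle, of the 8 genes with the largest increase and 7 of those with the largest decrease among well expressed genes whose groups did not overlap. Bars are limma estimates from 4 tumours per group and whiskers are 1 standard error, and the values run from 5.13 for Car3 to -3.89 for Agtr2.

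Genes of the cell cycle fell together, in the 4 libraries that also held higher macrophage (median 2.22) and fibroblast (median 2.16) markers. Foxm1, a transcription factor of G2 and mitosis, changed by -2.04 (SE 0.11), Ccnb1 (cyclin B1) by -1.74 (SE 0.11) and Kif20a, a kinesin of cytokinesis, by -1.83 (SE 0.12). The mitosis list was lower as a set (camera, adjusted p = 6.41e-11), and adjusted p = 0.397 with an estimated correlation. Among the replication genes Ccnd1 (cyclin D1) changed by -2.36 (SE 0.16), Rrm2, a ribonucleotide reductase subunit, by -2.12 (SE 0.12) and Ccna2 (cyclin A2) by -1.62 (SE 0.10), and Cdc6, Gins2 and Pola1, named after their values were seen, made no call. This list had adjusted p = 7.72e-11 (camera), and adjusted p = 0.397 with an estimated correlation. Of 20 homologous recombination and Fanconi repair genes, 14 fell and 6 made no call, with a median of -0.72. Fancd2 changed by -1.50 (SE 0.10) and Rad51ap1 by -1.38 (SE 0.14). With p-values adjusted over the list alone 14 fell and 1 rose, and over all genes 1 rose without vehicle library 1 or 2. The camera test gave adjusted p = 0.00139, and adjusted p = 0.508 with an estimated correlation.

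MYC and MYCN target genes, which serve ribosome biogenesis and growth, fell in 27 of 32 cases with a median of -0.85, in libraries with higher macrophage and fibroblast markers (medians 2.22 and 2.16). Dkc1, the pseudouridine synthase of small nucleolar ribonucleoproteins, changed by -1.75 (SE 0.13), the nucleolar protein gene Nop56 by -1.45 (SE 0.10) and Polr1b, an RNA polymerase I subunit, by -1.39 (SE 0.11). The list had adjusted p = 2.77e-06 (camera), and adjusted p = 0.508 with an estimated correlation. After quantile normalization 22 of these genes fell and 1 rose, with a median of -0.59. Cytoplasmic ribosomal protein genes fell in 27 of 34 cases with a smaller median of -0.46, among them Rpl6 at -0.67 (SE 0.14), Rplp0 at -0.64 (SE 0.13) and Rps13 at -0.61 (SE 0.13), none of which passed a test against a 1.5-fold change. Their camera test gave adjusted p = 2.11e-04, and adjusted p = 0.646 with an estimated correlation. The count of lower ribosomal protein genes was 17 after quantile normalization, with 1 higher, and 10 without panobinostat libraries 3 and 4. Mouse Mycn on chromosome 12 (12936093 to 12941914) fell by 0.86 (SE 0.20, adjusted p = 0.00408, limma, and 0.234 against a 1.5-fold change), from 7.45 ± 0.36 to 6.59 ± 0.29 log2 CPM (mean ± SD, n = 4). The transgene is human MYCN, and gene-level values do not show how many of its reads were assigned to the mouse gene.

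Most sympathoadrenal genes fell, in the libraries that also held adrenal cortex reads and higher macrophage, fibroblast and Schwann cell markers (medians 2.22, 2.16 and 2.32). Of the 24 members of the noradrenergic identity list 14 fell, 2 rose and 8 made no call, with a median of -1.31. Among those that fell were Tfap2b at -2.76 (SE 0.16) and Isl1 at -2.23 (SE 0.15), both transcription factor genes of sympathetic neurons. Adjusted over the list alone, 15 fell and 2 rose. The camera test gave adjusted p = 0.00238, and adjusted p = 0.508 with an estimated correlation. Several members were looked up after their values were seen. The vesicular monoamine transporter gene Slc18a1 rose by 1.12 (SE 0.31), a call that was lost without panobinostat libraries 3 and 4 (1.05, limma, adjusted p = 0.0759), and Ret rose by 0.52 (SE 0.18), a call that was lost without any of vehicle libraries 1, 2 and 3 and panobinostat libraries 2, 3 and 4 (adjusted p from 0.0507 to 0.0920, limma). The catecholamine synthesis genes Th (0.18, SE 0.31) and Dbh (0.12, SE 0.44) and the granule protein gene Chga (0.40, SE 0.22) made no call, while the synthesis gene Ddc fell by 1.46 (SE 0.21). Without panobinostat libraries 3 and 4, 13 members fell and 0 rose.

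Genes of maturing neurons were mostly lower, with 19 of 28 lower, 4 higher and a median of -0.91. Tubb3 (neuronal beta-tubulin) changed by -2.12 (SE 0.16), the neurofilament gene Nefh by -1.99 (SE 0.16) and the synaptic gene Cplx2 by -1.49 (SE 0.11). Among the members that rose, and named after their values were seen, were Prph (3.49, SE 0.82), Ngfr (3.03, SE 0.57) and Scg2 (2.69, SE 0.71). Prph encodes the intermediate filament peripherin, and Ngfr encodes a neurotrophin receptor and is also a Schwann cell gene. This list gave adjusted p = 0.00475 (camera), and adjusted p = 0.681 with an estimated correlation. Schwann cell markers were higher in the same 4 libraries, with a median of 2.32.

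Among genes often reported to rise with HDAC inhibitors, Hist1h1c, Gadd45b (3.36, SE 0.29) and the linker histone gene H1f0 (1.04, SE 0.10) had the smallest adjusted p. Cdkn1a on chromosome 17 (29090976 to 29100727), which encodes the cell cycle inhibitor p21, rose by 1.26 (SE 0.14, adjusted p = 7.07e-05, limma). Hist2h2be (0.15, SE 0.18) and the metallothionein genes Mt1 (0.20, SE 0.31) and Mt2 (-0.20, SE 0.37), named after their values were seen, made no call. Without vehicle library 3 the counts were 14 higher and 1 lower. The list gave adjusted p = 1.38e-04 (camera), and adjusted p = 0.397 with an estimated correlation. Stromal markers were higher in the same libraries (fibroblast median 2.16). Of the histone deacetylase genes themselves, 5 of 11 fell and none rose: Hdac10 (-1.06, SE 0.12), Hdac9 (-0.91, SE 0.14), Hdac7 (-0.86, SE 0.14), Hdac2 (-0.75, SE 0.10) and Hdac6 (-0.33, SE 0.10). The call of Hdac6 was lost without panobinostat library 1 or 3 (adjusted p = 0.0561 and 0.0583, limma), with quantile normalization (0.0692) and with scaling to read totals (0.0802). Hdac1 (0.16, SE 0.10) and Hdac5 (0.19, SE 0.14) made no call, but both rose under quantile normalization (0.36 and 0.46), scaling to read totals (0.28 and 0.31), library weights (0.23 and 0.31) and without vehicle library 4 (0.26 and 0.31). Hdac3 (-0.13, SE 0.10) fell only with median centring (-0.25) and was above 0 with quantile normalization (0.09), and Hdac11 (0.27, SE 0.40) rose only with library weights (0.78). Hdac4 (-0.00, SE 0.13) and Hdac8 (0.30, SE 0.18) made no call and changed sign with the scaling. As a set the deacetylase genes did not pass the test (camera, adjusted p = 0.244), though they did with fry (0.0179).

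Histone genes listed as having polyadenylated messages, linker histone genes among them, moved both ways, with 5 of 15 higher and 8 lower. Besides the linker histone genes H1f0 and Hist1h1c, Hist1h2bc rose by 2.54 (SE 0.21), whereas H2afy2, a macroH2A gene, changed by -2.46 (SE 0.15) and the linker histone gene H1fx, named after its value was seen, fell by 1.18 (SE 0.17). The list's median (-0.44) and mean (0.18) differ in sign, and camera made no call (adjusted p = 0.674). Reads of near-identical histone genes can be shared, so their values are uncertain. Of 18 chromatin regulators 13 fell and 2 rose, with a median of -1.09. The acetyltransferase gene Crebbp changed by -2.03 (SE 0.12) and Ezh2, the Polycomb methyltransferase gene, by -1.12 (SE 0.09). The Polycomb genes Cbx8 (1.19, SE 0.29) and Eed (0.41, SE 0.10) rose and were named after their values were seen, and without panobinostat libraries 3 and 4 both calls were lost (11 of the list fell and 0 rose). This list gave adjusted p = 2.11e-04 (camera), and adjusted p = 0.397 with an estimated correlation, in libraries whose macrophage markers were higher (median 2.22).

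In the libraries with higher macrophage and fibroblast markers (medians 2.22 and 2.16), targets of p53 rose in 14 of 24 cases and fell in 3, with a median of 1.16 (camera, adjusted p = 0.0225), and adjusted p = 0.397 with an estimated correlation. Dcxr rose by 2.67 (SE 0.21), Pmaip1, which encodes the BH3-only protein NOXA, by 3.22 (SE 0.28), and the antiproliferative gene Btg2 by 1.51 (SE 0.13). Bbc3 (-0.46, SE 0.13), Zmat3 (-0.91, SE 0.12) and Pvt1 (-1.09, SE 0.10) fell, and were named after their values were seen. Genes of the BCL2 family and the caspases moved both ways, with 11 of 24 higher and 8 lower (camera, adjusted p = 0.355). The BH3-only gene Bmf rose by 1.33 (SE 0.13), while Hrk, also of that class, changed by -2.22 (SE 0.13).

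In the same libraries, whose macrophage and fibroblast markers were higher (medians 2.22 and 2.16), unfolded protein response genes rose in 12 of 20 cases and fell in 3, with a median of 0.61 (camera, adjusted p = 0.0324), and adjusted p = 0.397 with an estimated correlation. Adjusted over the list alone 12 rose and 4 fell. Dnajc3 rose by 1.21 (SE 0.11), Sesn2 by 2.27 (SE 0.23) and Pdia4 by 1.54 (SE 0.16). The genes that fell, named after their values were seen, were Atf4 (-1.02, SE 0.19) and the amino acid synthesis genes Asns (-0.84, SE 0.16) and Psat1 (-0.82, SE 0.16). The camera call was lost without vehicle library 1 (adjusted p = 0.0597), and the count of lower genes was 6 with median centring. Heat shock genes rose in 6 of 14 cases and fell in 3 (camera, adjusted p = 0.453, and 0.0321 with fry). Hspa1a (3.43, SE 0.39) and Hspa1b (3.66, SE 0.43), near-identical HSP70 genes whose reads may be shared, rose, and Hsp90ab1 fell by 0.97 (SE 0.16).

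Hypoxia and glycolysis genes rose in 11 of 20 cases and fell in 3 (median 0.38, camera, adjusted p = 0.0968), and the counts were 9 and 1 without panobinostat library 3 and 7 and 1 without both 3 and 4. The list passed the threshold with quantile normalization (adjusted p = 0.0186, range over alternatives 0.0120 to 0.616). P4ha1, a collagen prolyl hydroxylase subunit, rose by 1.69 (SE 0.19), Aldoc by 2.10 (SE 0.26) and Pfkfb4 by 1.11 (SE 0.17). Cholesterol synthesis genes fell in 7 of 19 cases and rose in 1 (median -0.36, camera, adjusted p = 0.176). This list passed the threshold without panobinostat library 4 (adjusted p = 0.0383, range over alternatives 0.0178 to 0.746), and 2 genes rose without vehicle library 4. Without panobinostat libraries 3 and 4 it passed too, with 9 lower and 0 higher (adjusted p = 0.0178). The synthesis gene Lss fell by 1.10 (SE 0.16) and Acat2 by 1.23 (SE 0.22). Among panobinostat libraries, library 4 had the highest mean of the cholesterol synthesis genes (6.28 log2 CPM, lowest 5.61 in library 2). It also held the most reads of Cyp11b1 and Alb (6542 and 116170), and whether these go together was not tested. Fibroblast and macrophage markers were higher in the same panobinostat libraries (medians 2.16 and 2.22).

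Interferon-stimulated genes rose in 19 of 24 cases, and only Ifit2 fell (-0.65, SE 0.19, named after its value was seen), a call lost without panobinostat libraries 3 and 4. Adjusted over the list alone 20 rose and 1 fell. Stat2, a transcription factor of the type I interferon response, rose by 1.66 (SE 0.14) and Bst2 (tetherin) by 2.38 (SE 0.23). The list gave adjusted p = 1.77e-05 (camera), and adjusted p = 0.508 with an estimated correlation. In the MHC class I list, where 11 of 13 genes rose, Tapbp (tapasin) rose by 1.94 (SE 0.16), B2m (beta-2-microglobulin) by 2.28 (SE 0.26) and the immunoproteasome gene Psmb8 by 2.14 (SE 0.30). Its camera test gave adjusted p = 4.51e-04, and adjusted p = 0.508 with an estimated correlation. H2-K1 and H2-D1, named after their values were seen, also rose and are similar enough to share reads. Without vehicle library 3 the counts were 11 higher and 1 lower. Macrophages express many of these genes, and their markers were higher in the same 4 libraries.

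Macrophage markers rose in 14 of 16 cases, and in 16 of 16 when adjusted over the list alone. Ms4a7 rose by 3.10 (SE 0.16) and the complement gene C1qa by 2.52 (SE 0.20). The list gave adjusted p = 2.36e-06 (camera), and adjusted p = 0.508 with an estimated correlation. Markers of fibroblasts and mural cells rose in 15 of 16 cases, and adjusted over the list alone 15 rose and 1 fell. The counts over all genes were also 15 and 1 without vehicle library 1 or 2. The pericyte proteoglycan gene Cspg4 rose by 2.15 (SE 0.17) and the matrix gene Postn by 3.00 (SE 0.33). The camera test gave adjusted p = 1.44e-04 for this list, and adjusted p = 0.508 with an estimated correlation. Schwann cell markers rose in 9 of 12 cases, among them S100b (3.39, SE 0.41) and Gfap (2.74, SE 0.63), with adjusted p = 0.0209 (camera), and adjusted p = 0.508 with an estimated correlation. The count was 4 without panobinostat libraries 3 and 4 and 8, with 1 lower, without panobinostat library 2, and the call was lost with a filter of 5 CPM (adjusted p = 0.135, range over alternatives 0.00630 to 0.508).

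Endothelial markers moved less. Of 18 genes 3 rose (Tek, named after its value was seen, Flt1 and Eng), and 0 when adjusted over the list alone, with a median of 0.49 (camera, adjusted p = 0.188). Without vehicle library 1 the count was 7 and the list passed the threshold (adjusted p = 0.0359), without panobinostat library 1, 2 or 3, or both 3 and 4, the count was 1, and without vehicle library 3 the median was 0.01 and 1 gene fell. Few lymphocyte genes were measured. Of 3 tested T and NK cell genes Thy1 rose by 2.03 (SE 0.22), Cd4, named after its value was seen, rose by 1.77 (SE 0.42) and Lck fell by 1.31 (SE 0.24), and of these Thy1 is also expressed by neurons and fibroblasts. Cd3e and Cd8a stayed below the filter, with at most 76 reads in any library. Of 6 B and plasma cell genes 1 rose, Cd22 (1.21, SE 0.33), and 5 rose without vehicle library 1, which held 58 reads of Mzb1 where each of the other vehicle libraries held 9. With quantile normalization 0 rose, and Cd22 changed by 0.71 (adjusted p = 0.0687, limma). For granulocyte genes 2 of 6 rose (1 adjusted over the list alone), Mmp8 (2.80, SE 0.36) and Csf3r (0.82, SE 0.28), and 1 rose without vehicle library 2 or 3 or panobinostat library 1, 2 or 3. Of 6 erythroid genes 1 rose, Epor (1.16, SE 0.45), and 0 when adjusted over the list alone, without vehicle library 3 or 4 or without panobinostat library 2, 3 or both 3 and 4. Without panobinostat library 1 none rose and 5 fell, among them Alas2 (-1.52). These lymphoid, granulocyte and erythroid lists did not pass the camera test, with adjusted p = 0.453, 0.420, 0.355 and 0.750 for T and NK, B and plasma, granulocyte and erythroid genes, but the B and plasma cell list did without vehicle library 1 (adjusted p = 0.0397).

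**Figure D2:**
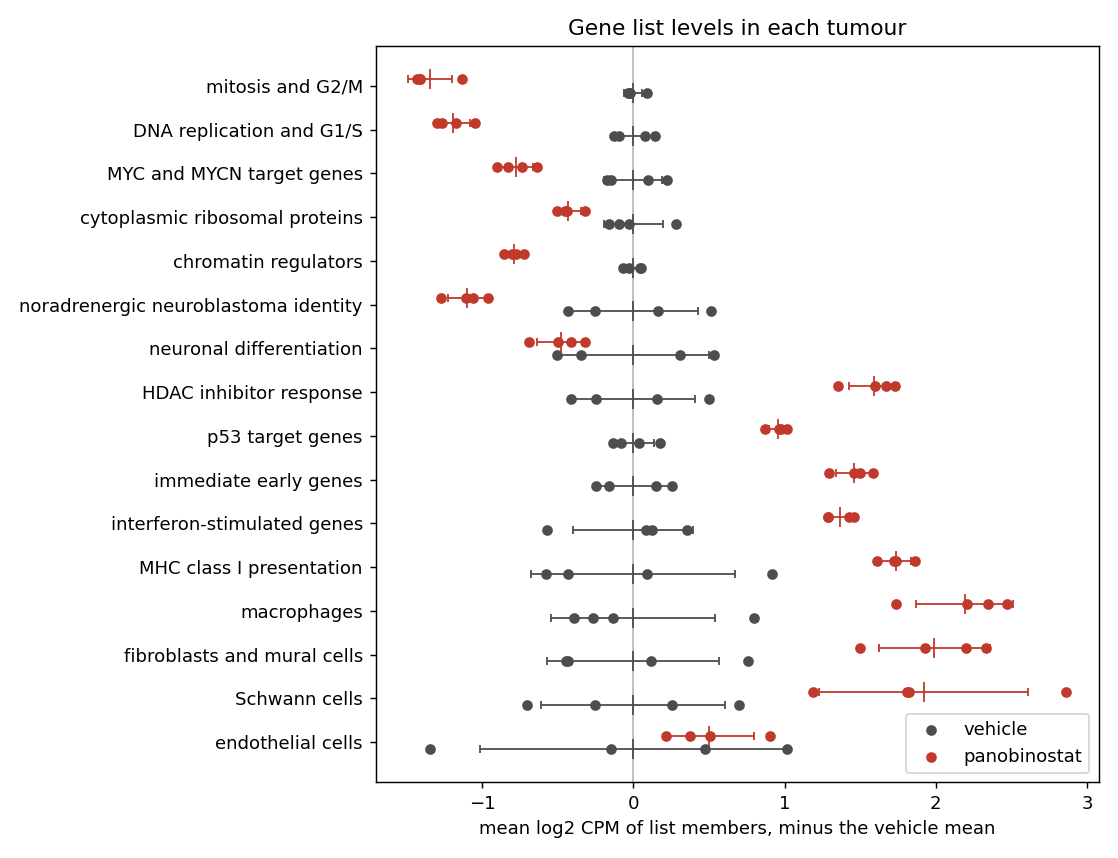
Mean log2 CPM of the members of 16 gene lists in each tumour, minus the mean of the 4 vehicle tumours. Points are single tumours, ticks are group means and whiskers are 1 SD over 4 tumours. Panobinostat tumours lie below all vehicle tumours for mitosis and DNA replication genes and above them for macrophage markers, while the groups overlap for endothelial and neuronal differentiation genes.

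Genes of neighbouring organs were read mainly in panobinostat libraries, with the organs differing between libraries except for the adrenal cortex, which was read in all 4. Cyp11b1, the last enzyme of corticosterone synthesis in the adrenal cortex, had 1 to 4 reads in each vehicle library and 2126, 54, 2390 and 6542 reads in panobinostat libraries 1 to 4. Of 8 tested adrenal cortex genes 7 rose (camera, adjusted p = 0.00291), and adjusted p = 0.508 with an estimated correlation. The call was lost with a filter of 5 CPM (adjusted p = 0.0654) and with voom weights (0.0506), where the lowest value of any alternative was 1.07e-05. Alb (albumin) had 39 to 107 reads with vehicle and 363, 179, 8715 and 116170 with panobinostat. Amy2a5 (pancreatic amylase), named after its values were seen, had 6 to 19 reads with vehicle, 4580 in panobinostat library 2 and 29872 in library 4, against 19 and 23 in libraries 1 and 3. Kap, a kidney androgen-regulated gene named after its values were seen, had 9563 reads in panobinostat library 3 and at most 68 elsewhere. Kidney genes were tested in 3 cases, of which 2 rose (camera, adjusted p = 0.284), and 1 rose without vehicle library 1, 3 or 4. Of 2 tested pancreas and liver genes both rose, too few for a list test, and 1 rose without any of vehicle libraries 1 to 4 or panobinostat library 2 or 3.

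**Figure D3:**
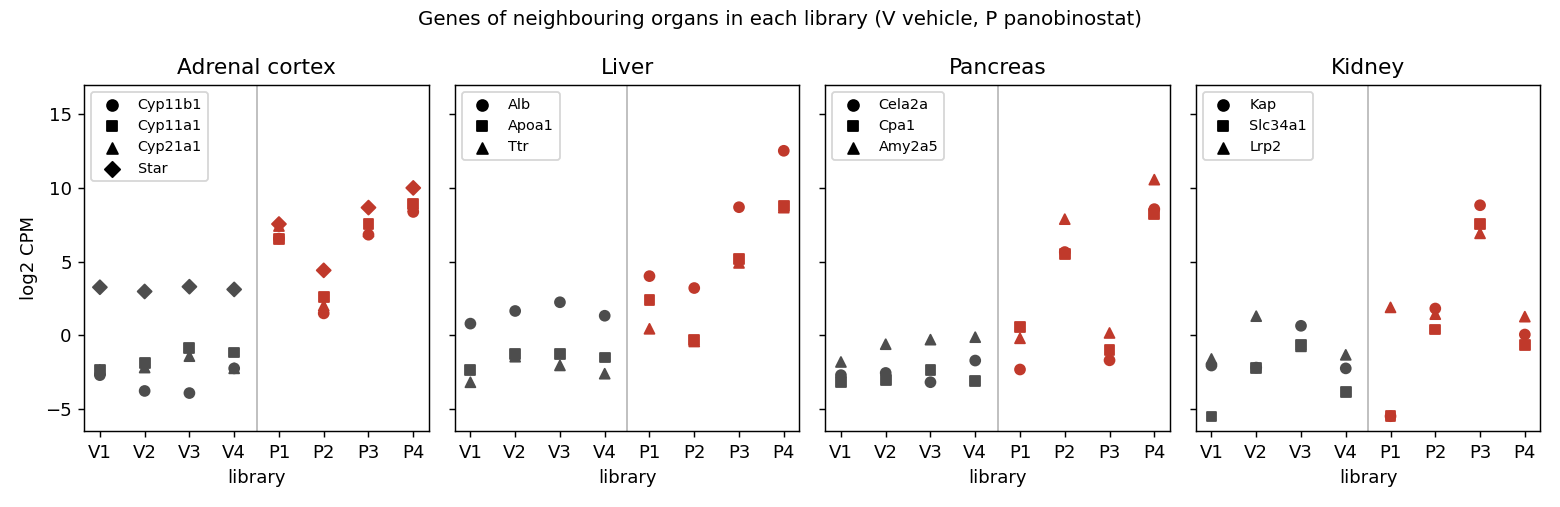
Log2 CPM of genes of the adrenal cortex, liver, pancreas and kidney in each of the 8 libraries (V, vehicle, P, panobinostat). Each point is a gene in a single library. Adrenal genes are high in panobinostat libraries 1, 3 and 4 and lower in library 2, where those shown still exceed vehicle. Liver genes are highest in 3 and 4 and exceed vehicle in 1 and 2 too. Pancreas genes are high in 2 and 4, and kidney genes in 3.

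Immediate early genes, which respond to tissue handling as well as to signalling, rose in 11 of 14 cases, and 1 fell, Dusp1 (-0.37, SE 0.12, named after its value was seen), which lost its call without panobinostat library 2 or 4 or both 3 and 4. Arc rose by 2.98 (SE 0.23), in libraries whose macrophage markers were higher (median 2.22), and the list had a median of 1.74 (camera, adjusted p = 0.00139), and adjusted p = 0.397 with an estimated correlation. Mitochondrially encoded genes rose in 3 of 13 cases, and 1 when adjusted over the list alone, with a median of 0.51 (camera, adjusted p = 0.0623). The list passed the threshold without vehicle library 1 or 2 (adjusted p = 0.0403 and 0.0138) and with a filter of 5 CPM (0.0488), and the count was 5 and 6 without vehicle libraries 1 and 2 and 1 without vehicle library 3, panobinostat library 1 or panobinostat libraries 3 and 4 together. Without vehicle library 4 the count stayed at 3 and the median was 0.26. Of the members mt-Nd3 rose by 0.81 (SE 0.16) and mt-Co3 by 0.57 (SE 0.18), a call lost without vehicle library 3 (adjusted p = 0.0743, limma) or panobinostat library 1 (0.0544).

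Pearson's r between libraries was 0.938 to 0.971 within vehicle, 0.947 to 0.980 within panobinostat and 0.810 to 0.878 between groups. The first principal component carried 70.6% of the variance and separated the groups. Vehicle tumours lay farther apart than panobinostat tumours (mean 1 minus r of 0.0476 and 0.0324), a difference of -0.0152 (two-sided exact permutation over 35 splits, p = 0.286). The other splits mix the groups, so their distances hold the group difference, and this p-value does not measure spread within groups. The median SD of a gene was 0.296 with vehicle and 0.156 with panobinostat. With no filter on low values the difference of mean distances was 0.0221. Of 31 gene lists tested with camera 18 passed the threshold, 10 higher and 8 lower, and 0 did so with an estimated correlation (3 at an unadjusted p under 0.05), while fry, which tests each list without setting it against other genes, called 21. Each library holds tumour and stroma together, so changes in tumour cells and in the makeup of the sample are read as a sum.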

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

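The tests of organ genes, of stromal markers against endothelial markers and against all genes (library scaling), and of noradrenergic genes against cell cycle genes were chosen only after the results were seen, while the tests of sample splits and of transcript length and GC content were written before. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, called 10289 genes or more with limma. The highest count of any other was 0 (2283 at an unadjusted p under 0.05, against 10873 for the real split). Every other split mixes the 2 groups, so the group difference widens its residual spread and few calls could be made. The splits therefore cannot exclude chance, nor a difference between the groups other than the drug.

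Genes of the adrenal cortex, liver, pancreas and kidney were higher with panobinostat, but not to the same degree in each tumour. The median SD of 11 such genes between the 4 panobinostat libraries was 15.3 times that of 498 genes of similar level that also rose (2.71 against 0.176), and the highest ratio of 2000 random sets was 2.64. The comparison genes had to be called higher, which selects a low SD, and the random sets were drawn from them. Organ genes also vary together, so this ratio cannot decide. The reads themselves were unequal in panobinostat libraries 1 to 4, at 2126, 54, 2390 and 6542 for Cyp11b1 and 363, 179, 8715 and 116170 for Alb. For these genes they argue against a drug response of like size in the 4 tumours. Pieces of neighbouring organs in the panobinostat samples would give unequal reads. Adrenal reads were in all 4 libraries, fewest in library 2, pancreas reads in 2 and 4, and kidney reads in 3. Why vehicle tumours held so few of these reads was not tested, and a smaller tumour at harvest may be a reason that the values here cannot address.

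Macrophage markers and fibroblast and mural cell markers rose more than endothelial markers did. Relative to the endothelial score the macrophage score rose by 1.69 (pooled SD 0.57) and the fibroblast and mural cell score by 1.49 (pooled SD 0.44), both with a two-sided exact permutation p = 0.0286, the smallest possible (Benjamini-Hochberg 0.0429, n = 4 per group). A lower share of tumour cells as the only change would raise all of these markers alike. The endothelial list was made the reference after its smaller change was seen, and its vehicle scores varied widely (SD 1.02). The unequal rise therefore cannot decide against a lower tumour share. The library scaling moves all genes of a library alike. It is argued against, since these and Schwann cell markers rose by 1.93 (pooled SD 0.30) relative to the median of all tested genes. For Schwann cells the rise over endothelial markers was 1.42 with a pooled SD of 1.29 (two-sided exact permutation p = 0.200, n = 4 per group), too wide a spread to set these lists apart. A lower share of tumour cells, more stromal cells, higher expression of these genes in the cells present, and a fall of endothelial cells all remain open, and a response of stromal genes to panobinostat may contribute.

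Cell cycle and MYC target genes fell, and so did most genes of sympathoadrenal identity. The score of the whole noradrenergic list changed by 0.17 relative to the cell cycle score (SE 0.22, two-sided exact permutation p = 0.486, n = 4 per group), with medians of -1.31 and -1.29. A difference of means within its error does not show an equal fall. For the cell cycle genes, dilution of tumour RNA by other cells therefore cannot be told apart from lower expression. The interquartile range was 2.21 between the 24 noradrenergic genes and 0.40 between the cell cycle genes. Dilution as the only change would lower genes read from tumour cells alone by a like amount. The noradrenergic list was not limited to such genes. Its wide range cannot decide against dilution as the only change, because other tissue may have held some members up. Adrenal medulla may do so, and its gene Pnmt, named after its values were seen, cannot tell in which libraries. Pnmt had 491, 20, 50 and 260 reads in panobinostat libraries 1 to 4. Vehicle libraries held 69 to 222 reads of it beside 1 to 4 of Cyp11b1, so its reads may not come from medulla alone. The trend with transcript length and GC content is argued against, since it held only 0.836% of the variance of the changes and its removal moved the median of these genes (from -1.18 to -1.35) about as far as that of all genes (from -0.02 to -0.20). For cell cycle and MYC target genes a panobinostat effect on expression remains open beside dilution.

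In 10 of 262 groups of 4 libraries a single library lay far from the other 3, where chance gives about 1 in 20, or 13.1. In panobinostat library 1, H1f0 was at 9.65 log2 CPM (nearest other 9.83) and mt-Co3 at 12.95 (nearest other 12.67). In panobinostat library 3, Lrp2 was at 6.93 (nearest other 1.90) and Prr36 at 3.41 (nearest other 3.66). Panobinostat library 4 had Pfkfb4 at 4.52 (nearest other 4.86) and a mean of the mitosis genes of 6.26 (nearest other 5.98). Vehicle library 1 had Mzb1 at 1.37 (nearest other -1.10). Vehicle library 2 had P4ha1 at 4.49 (nearest other 5.15) and a mean of the mitosis genes of 7.48 (nearest other 7.37). Vehicle library 4 had Hdac1 at 6.83 (nearest other 6.46).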

How the results depend on the processing

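Scaling to read totals, voom weights and leaving out panobinostat libraries 3 and 4 were chosen after the data were seen. Of 104 named genes 76, and of 31 gene lists 5, kept direction and side of the threshold under every alternative run for them, as did 2084 of 2174 values of genes and 584 of 618 of lists. The test against a 1.5-fold change called 4988 genes, 2802 higher and 2186 lower, fewer because it asks for larger changes. The other settings gave 7828 to 11420 changed genes, and leaving out single libraries 9175 to 10467. Gene lists past the threshold numbered 18 to 20 without single libraries and 0 with an estimated correlation. The median change of all genes was -0.02, against -0.14 with quantile normalization or median centring and 0.10 with read totals, and changes are read relative to it.

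The difference in spread between groups was 0.0221 with no filter (two-sided exact permutation, p = 0.629) and ran from -0.0221 to -0.00658 without single libraries. Sign changes, none past the threshold, were seen for Hdac3 (0.093) and Hdac8 (-0.238) with quantile normalization, and for Hdac4 with trimmed mean centring (0.015), read-total scaling (0.118), voom weights (0.0016) and without panobinostat libraries 3 and 4 (0.128). Without single libraries Hdac4 ran from -0.065 to 0.067 and Hdac11 from -0.013 to 0.593. The erythroid list had a median of 0.343 without panobinostat libraries 3 and 4. The cause was not tested for any of these. The planned count-model tests were not run, although whole reads could be recovered. The deposited logarithms were tested instead, and limma with voom weights on the recovered reads called 10255 genes. No paired analysis was possible because the replicate numbers only name the animals. Depth limits genes near 1 CPM, or 19.3 to 22.6 reads, where single reads move a value.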

Other observations

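The 5 gene lists here were written after the values were seen, and so were their tests. Their p-values, adjusted over these lists alone, therefore cannot count as support. Genes of adipocytes rose in 11 of 13 cases (median 3.33, camera, adjusted p = 0.00266), and adjusted p = 0.356 with an estimated correlation. Plin1, which coats lipid droplets, rose by 3.37 (SE 0.82), from 27 to 502 reads in the vehicle libraries to 791 to 1111 reads with panobinostat. Lysosome and autophagy genes rose in 18 of 23 cases (median 1.40, camera, adjusted p = 6.61e-07), and adjusted p = 0.183 with an estimated correlation. Among them were the cathepsin genes Ctsb (2.46, SE 0.19) and Ctsl (2.41, SE 0.22) and Tfeb (1.81, SE 0.21), a transcription factor of lysosome genes. All 11 complement genes rose (median 1.86, camera, adjusted p = 0.00106), and adjusted p = 0.255 with an estimated correlation, with C1s1 at 2.80 (SE 0.42). Macrophages express many lysosome and complement genes, and their markers had a median rise of 2.22 in the same libraries.

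In the libraries with higher macrophage markers (median 2.22), genes of chromatin remodellers and lysine methyltransferases fell in 18 of 20 cases (median -1.07, camera, adjusted p = 1.62e-06), and adjusted p = 0.183 with an estimated correlation. Arid1a changed by -1.77 (SE 0.09), Setd1b by -1.82 (SE 0.19) and Smarca4, a SWI/SNF ATPase gene, by -1.58 (SE 0.14), while the ATPase gene Smarca2 rose by 1.36 (SE 0.17). Imprinted genes moved both ways, with 9 of 16 lower and 3 higher (camera, adjusted p = 0.0815). Dlk1 changed by -1.55 (SE 0.14) and Sgce by -1.79 (SE 0.21), and Igf2 rose by 3.19 (SE 0.48). By mean level, 1153 genes of the least expressed quintile were higher and 452 lower, against 626 higher and 1672 lower in the most expressed quintile.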
